A study of Mus musculus with 27 samples.

How the data were processed

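The series profiled DNA methylation by reduced representation bisulfite sequencing (RRBS) in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. Per the labels' protocols, myoblasts were differentiated in medium with 2% horse serum, the cells were shocked with 50% horse serum for 2 h, and DNA was digested with a restriction enzyme, bisulfite converted and ligated to sequencing adapters. The labels write the enzyme as MpsI; RRBS commonly uses MspI, which cuts at CCGG sites, so that the measured CpGs lie in short fragments that are rich in CpG islands and gene starts. Per the labels, libraries were made every 6 h from 12 h to 60 h after the serum shock, with 3 replicates at each of 9 time points, 27 libraries in all. The labels do not say whether the replicates came from separate cultures or plates, so the p-values measure only the spread between these samples, which may be technical.

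Per the submitters' processing notes, the tools used were Trim Galore 0.4.0, cutadapt 1.9.1, Bismark 0.14.4 and Bowtie2, and the genome build was mm10; the order of steps and their settings are not given in the sources used here. The authors deposited a single table for the whole series, with 1 row per genomic position and 1 column per library, whose values are methylation levels as a fraction from 0 to 1, per the file headers and the values. Each library column was matched to its sample by the time point and replicate number in its name. The table holds no read counts and no coverage, so the depth behind each level is unknown, no confidence interval from read counts can be given, and nothing was weighted by depth. What the values show is that levels at neighbouring positions are not independent. The deviations of a library from the mean over all 27 libraries had a Pearson correlation of 1.00 between positions 1 bp apart. It was 0.591 between positions 41 to 60 bp apart, 0.234 at 61 to 80 bp and 0.00692 at 81 to 100 bp, across positions, which are not independent replicates. No run of positions with gaps of up to 100 bp held fewer than 5 positions. Neighbouring levels therefore share information. The cause was not tested and is not given in the sources used here. Of the neighbouring pairs, 279667 lay 1 bp apart, with a mean difference of 0.0698 points, so such pairs hardly count as separate measurements. A count of positions is not a count of independent events, and called positions were joined into site groups where they lay within 80 bp of each other.

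Of 937644 positions, the 871894 (93.0%) with a value in all 27 libraries were kept, and 217225 of them had a mean level between 10% and 90%. Levels were multiplied to percent, so that differences are in percentage points. Regions were runs of kept positions with gaps of at most 200 bp and at least 3 positions (18447 regions, median 32 positions). A promoter table was planned, but the gene table used here (the RefSeq annotation of GRCm38.p6, the assembly that mm10 names) gives gene starts and ends without strand. Windows at both ends of each gene therefore took the place of promoters, from 1000 bp outside the gene to 500 bp inside it, with at least 3 kept positions. This gave 12512 windows of 11952 genes, of which 560 genes had both; a window is called here the lower or higher end by its coordinate, and it can be the start or the end of the gene. Exons, introns and untranslated regions are not annotated here. Coordinates are printed as in the deposited table, whose counting from 0 or 1 is not given in the sources used here.

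The planned count model could not be used without read counts, so the test laid down for levels was used: limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the data.table package), a linear model with empirical Bayes moderation on percentage points over all 27 libraries, which share 1 estimate of the spread. The tests were a 24 h cosine and sine (the rhythm), the time point as a factor (any difference between time points), linear time (the trend, as points per 48 h) and 60 h against 12 h. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Amplitudes and slopes carry the model's standard error (SE), and an upper 95% limit of the amplitude states what size of rhythm is left open; it is the fitted amplitude plus the margin that the F distribution gives. Means over time for whole libraries and the similarity of libraries 24 h apart against 12 h and 36 h apart were tested with 100000 permutations of the time labels (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; figures with matplotlib 3.10.9). All tests are two-sided unless stated. The comparison of a list's mean amplitude with random lists is one-sided, for larger amplitudes.

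The 13 gene lists hold core clock genes, myogenic regulators, muscle structure genes, cell cycle genes, DNA methylation enzymes, glucose metabolism, lipid and mitochondrial metabolism, imprinted genes, germline genes, Hox and other developmental genes, immediate-early serum response genes, and markers of 2 kinds of other cells (fibroblasts and adipocytes, immune and neural cells). They name 408 genes, all matched to a symbol, of which 267 had a window. Each list was tested with camera at its preset correlation of 0.01 and with an estimated correlation, and its mean 24 h amplitude was set among 10000 random lists of the same size matched on mean level. The rule for named genes took the 10 largest effects in each direction among features that passed. Where fewer passed, it took all that passed and the smallest p-values up to 5 in all, given as not passing. It also took 10 core clock genes for the rhythm, 15 myogenic, metabolic and methylation genes for the trend, the 2 smallest p-values of each list, and the 5 highest and 5 lowest windows of the imprinted and germline lists. A region and a site group that this rule took are not reported here. The grouping, tests, lists, naming rule and alternative settings were set before the data were examined.

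The models were tested on simulated data in which rhythms, trends and shifts of 2, 5, 10 and 20 points were added to 200 features. Before that, the real levels of each feature were shuffled over the libraries separately, which removed the likeness of neighbouring features. Trends and shifts went up or down at random. All changes were cut at the ends of the scale, so downward changes at low levels were cut short. The report gives the share recovered beside the test it belongs to. The alternative settings were M-values (log2 of the level over its complement, offset 0.01), a replicate block, the library mean as a covariate, trended and robust moderation, periods of 20 h and 28 h, a linear or a 24 h term beside the other, positions of 10% to 90% only, 2 of 3 values per time point (922260 positions), regions with gaps of 50 bp or at least 5 positions, windows of 200 bp and 2000 bp on each side, and leaving out each library and each replicate number. Chosen after seeing the data were a fit on 1 position per 80 bp (96222 positions), tests of regions and windows between time points, and each time point against all others. Time labels were also redrawn 100 times over all 27 libraries, without regard to replicate number.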

Results

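DNA methylation was measured by RRBS in C2C12 myotubes, cells of a mouse muscle line, after a 2 h serum shock, a treatment used to bring the circadian clocks of cultured cells to a common phase. The 27 libraries covered 9 time points from 12 h to 60 h in steps of 6 h, with 3 libraries each, and libraries of unshocked cells were not analysed here. A methylation level was present in every library at 871894 positions, and the number of reads behind each level is unknown. A library lacked a value at between 1640 positions (48 h, replicate 2) and 21925 positions (12 h, replicate 3). The share of kept positions at exactly 0 ranged from 5.15% (24 h, replicate 3) to 25.4% (12 h, replicate 3). Across positions, which are not independent replicates, the Pearson correlation of a pair of libraries lay between 0.876 and 0.957 over 351 pairs, and its mean was 0.920 within a time point and 0.921 between time points, so no pair of libraries stood out as copies of each other.

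The baseline pattern of the cells was the first question. Ends of germline genes were the most methylated of the 13 gene lists, with a median of 82.5% over 19 windows. Ddx4, an RNA helicase of germ cells, stood at 93.0% ± 3.46 (SD over 27 libraries). Tdrd1 (92.9%), Mael (92.5%) and Dazl (91.2%), which act in transposon silencing or germ cell translation, and Sycp3 (88.8%), a part of the meiotic chromosome axis, followed. The lowest germline windows were those of Dppa4 (49.5% ± 10.4), Pou5f1 (54.9%), Zfp42 (67.7%), Dppa3 (69.0%) and Rpl10l (69.4%), of which Dppa4, Pou5f1, Zfp42 and Dppa3 are genes of pluripotent or early embryonic cells. Imprinted genes, of which only 1 parental copy is expressed, had a median of 44.1% over 21 windows. Peg10 lay at 44.1% ± 10.8, Igf2r at 46.9% ± 12.7 and Peg3 at 46.6% ± 21. The highest were Nnat (96.7%), Magel2 (70.4%), Nap1l5 (69.6%), Snurf (59.3%) and Grb10 (58.9%) and the lowest Herc3 (2.04%), H13 (2.07%), Trappc9 (2.69%), Inpp5f (3.45%) and Dlx5 (12.9%).

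Other lists differed as widely in level. Hox and other developmental genes had a median of 20.1% (48 windows), immune and neural markers 27.8% (9), muscle structure genes 13% (14), fibroblast and adipocyte markers 8.49% (10), myogenic regulators 5.27% (18) and glucose metabolism genes 5.20% (32). Core clock genes had a median of 4.06% (23), immediate-early genes 3.20% (27), DNA methylation enzymes 2.66% (15), lipid and mitochondrial genes 2.42% (29) and cell cycle genes 2.38% (21). Among muscle genes, the giant sarcomere protein gene Neb stood at 78.8% ± 2.79 and the fast troponin gene Tnni2 at 78.1% ± 8.51, against 3.72% ± 5.49 for the fast myosin light chain gene Mylpf and 3.36% ± 2.21 for the tropomyosin gene Tpm1. Over all 12512 windows the median was 3.73%, with 69.5% of windows under 10% and 8.0% at 50% or more. Against 10000 random lists of windows of the same size, the list medians of the germline, imprinted and Hox lists lay above all random medians. The immune and neural list (percentile 99.2) and the muscle structure list (percentile 97.0) lay high as well. Those of the lipid and mitochondrial list (percentile 1.04) and the cell cycle list (percentile 1.99) lay low. These windows can be the start or the end of a gene, since strand was not used, so a high level does not say that a promoter was methylated.

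**Figure D1:**
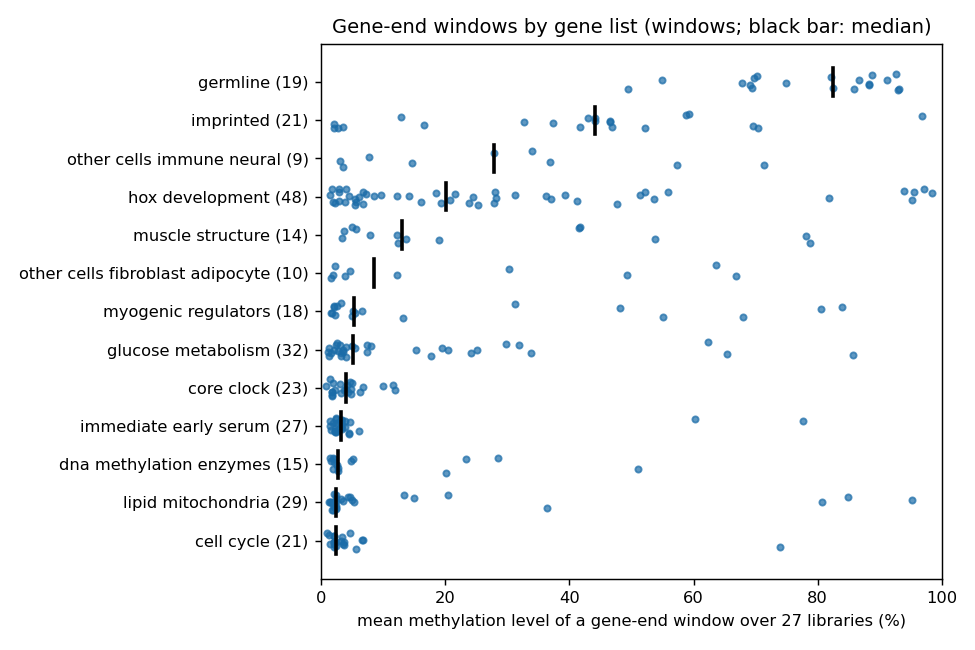
Mean methylation level (percent, x axis) of each gene-end window over 27 libraries, for the 13 gene lists (y axis, number of windows in brackets); points are windows and black bars list medians. The germline median lies at 82.5%, the imprinted median at 44.1%, and 21 of the 23 core clock windows lie under 10%.

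Gene ends on the X chromosome stood apart from those on autosomes. The median X window was at 33.4% (quartiles 27.7% and 40.5%; 366 windows) against 3.58% for 12146 autosomal windows, and 92.9% of X windows had a level from 10% to 75%, against 25.4% of autosomal windows. X-linked housekeeping genes such as Pgk1, a glycolytic enzyme (25% ± 6.10), and Pdha1, a subunit of pyruvate dehydrogenase (33.8% ± 6.95), lay in this range. Averaged over time points, the mean level of X positions lay between 36.8% ± 3.00 (12 h; SD, n = 3) and 39.3% ± 2.56 (24 h).

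**Figure D2:**
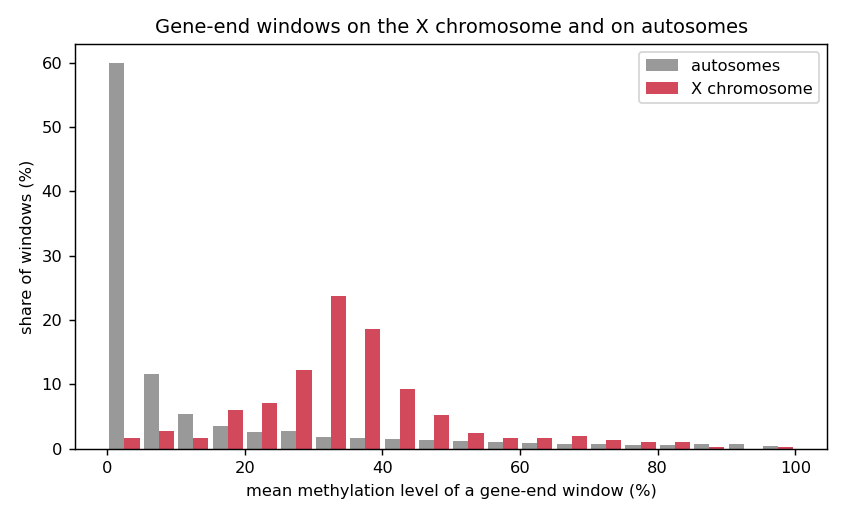
Share of gene-end windows (percent, y axis) in bins of 5 points of mean methylation level (percent, x axis), for 366 windows on the X chromosome and 12146 on autosomes. The most filled bin of the X chromosome is 30% to 35% (23.8% of windows), and 59.9% of autosomal windows lie under 5%.

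Whether the genome-wide level drifted or cycled after the serum shock was asked with the mean of each library. Library means lay between 11.4% (12 h, replicate 3) and 12.7% (48 h, replicate 3), and the time point means between 11.8% ± 0.138 at 60 h and 12.1% ± 0.503 at 48 h (SD, n = 3). The range of the time point means, 0.371 points, was close to the pooled SD within time points of 0.342 points. No difference between time points was detected (permutation p = 0.942, adjusted 0.963 over 3 tests), and the 24 h amplitude of 0.132 points (SE 0.0832) was not detected as a rhythm either (permutation p = 0.282, adjusted 0.846). The slope was -0.00857 points per 48 h (SE 0.186; permutation p = 0.963, adjusted 0.963). These tests did not take replicate number into account. Without replicate 3 of 48 h the range was 0.172 and the amplitude 0.0843 points, and without replicate 2 of 12 h the range was 0.660 points. The sign of the slope rested on single libraries: it was 0.106 without replicate 2 of 12 h, 0.0402 and 0.00141 without replicates 2 and 3 of 18 h, 0.0330 without replicate 3 of 24 h, 0.00187 without replicate 3 of 30 h, 0.0382 and 0.00657 without replicates 1 and 2 of 54 h, 0.0458 and 0.00386 without replicates 1 and 2 of 60 h, and 0.251 without all libraries numbered 2. Without those libraries the range was 0.817 and the amplitude 0.239 points.

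**Figure D3:**
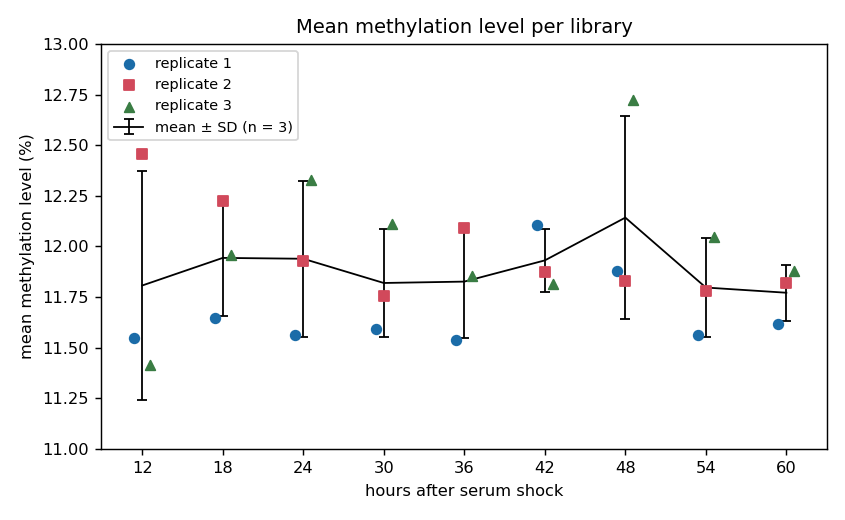
Mean methylation level (percent, y axis, from 11% to 13%) of each of the 27 libraries against hours after the serum shock (x axis); symbols mark replicate numbers, and the line joins the time point means with bars of 1 SD (n = 3). Libraries lie between 11.4% and 12.7%, and the time point means span 0.371 points.

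A 24 h rhythm at the genes of the circadian clock was the central question of a serum-shock time course. The ends of clock genes were little methylated throughout. The transcriptional activator gene Clock had a level of 9.91% ± 2.22 (SD over 27 libraries), the repressor genes Per1, Per2 and Per3 3.67% ± 3.64, 1.75% ± 1.54 and 4.78% ± 1.15, and Cry1 and Cry2 1.97% ± 1.14 and 1.76% ± 1.36. The nuclear receptor genes Nr1d1 and Nr1d2, which repress Arntl, stood at 3.15% ± 1.96 and 1.71% ± 1.14, and the output gene Dbp at 4.15% ± 2.14. Arntl had no window. Fitted 24 h amplitudes were 0.817 points for Clock, 1.21 for Per1, 0.526 for Per2, 0.515 for Per3, 0.247 for Cry1, 0.290 for Cry2, 0.562 for Nr1d1, 0.243 for Nr1d2 and 0.588 for Dbp, and their upper 95% limits were 2.47, 3.88, 1.70, 1.39, 1.16, 1.35, 2.05, 1.15 and 2.2 points in the same order.

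None of the 23 core clock windows passed (limma, 0 at an unadjusted p under 0.05; 0 adjusted over the list alone, smallest adjusted p 0.791). Amplitudes of the list ran from 0.242 to 1.91 points and upper limits from 1.07 to 4.60 points. The smallest unadjusted p-values were those of Timeless (0.0514), a replication and clock partner gene at 0.749%, and Tef (0.169), a transcription factor gene of the clock output at 5.03% ± 3.80.

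Of the other lists, 1 window passed when p-values were adjusted over the list alone, and 0 when they were adjusted over all windows. It was the lower end of Myod1, which encodes the transcription factor that commits cells to muscle (mm10 chromosome 7, 46375474 to 46376974, gene at 46376474 to 46379092). Its level was 55.1% ± 5.44 over 27 libraries, with 63.4% ± 1.25 at 24 h and 59.0% ± 3.60 at 48 h (SD, n = 3) against 50.4% ± 6.72 at 12 h, 54.6% ± 5.40 at 36 h and 49.8% ± 1.91 at 60 h. The amplitude was 4.73 points (SE 1.15, upper 95% limit 7.86), with an adjusted p of 0.0158 over the 18 windows of the list alone and 0.967 over all windows. The call did not pass on the M-value scale (adjusted p 0.0722 over the list alone), at periods of 20 h (0.811) and 28 h (0.242), without replicate 2 (0.0562) or replicate 3 (0.0516) of 24 h, or without all libraries numbered 1 (0.377) or 3 (0.170). Over its other alternatives and leave-outs the adjusted p lay between 0.00229 and 0.0460.

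**Figure D4:**
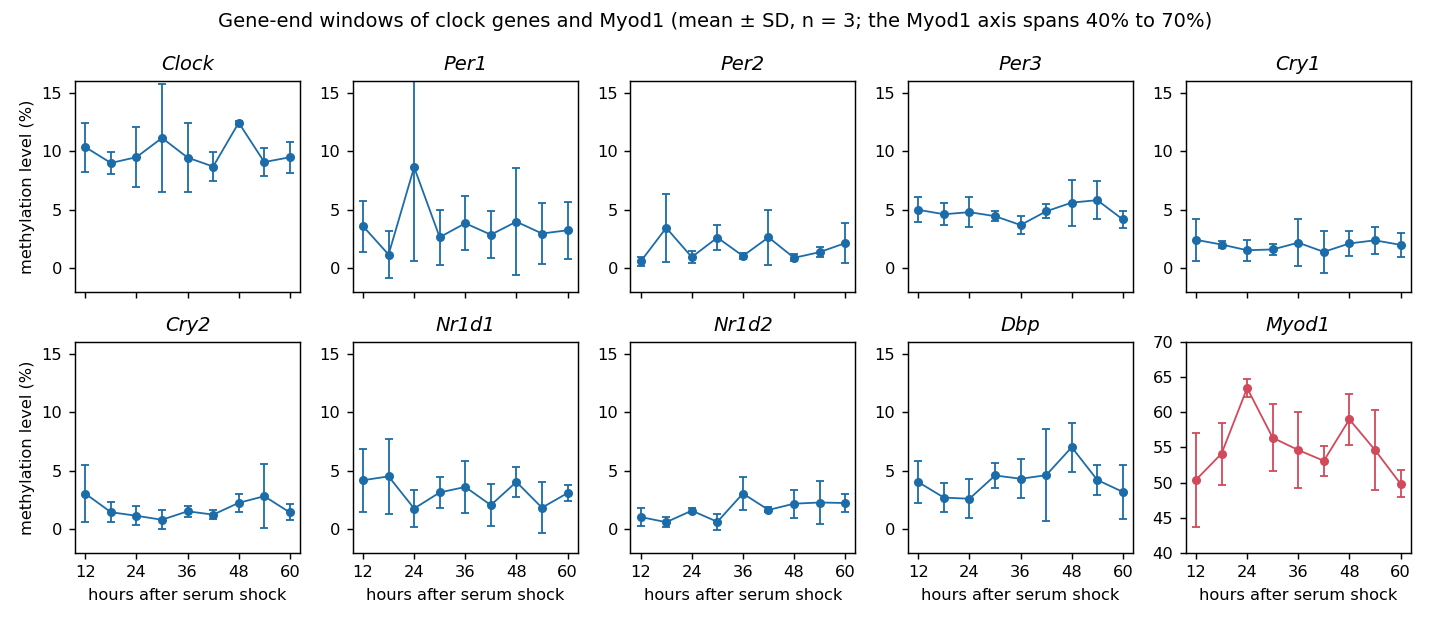
Methylation level (percent, y axes) of the gene-end windows of 9 clock genes, drawn from -2% to 16%, and of Myod1, drawn from 40% to 70%, against hours after the serum shock (x axes), as mean ± SD of 3 libraries. The upper part of the Per1 bar at 24 h leaves the panel (8.64% ± 8.04); Myod1 has its highest means at 24 h (63.4%) and 48 h (59.0%).

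In the other lists the smallest rhythm p-values, none of which passed, belonged to Eya2 (0.181) among myogenic regulators, the calcium release channel gene Ryr1 (0.110) and the actinin gene Actn3 (0.120), the cyclin gene Ccnb2 (0.0735) and E2f2 (0.107), and the methyl-CpG binding protein genes Mbd1 (0.0574) and Mbd3 (0.0793). Among metabolic genes they belonged to Pkm (0.0140) and Ldha (0.0519), which act at the end of glycolysis, to Fabp3 (0.135), a fatty acid carrier, and to Angptl4 (0.185). Mcts2 (0.0422) and Dlx5 (0.0460) led the imprinted list, Mael (0.00924) and Zfp42 (0.0263) the germline list, and Hoxb7 (0.0140) and Hoxb5 (0.0199) the developmental list. The fibroblast marker Fn1 (0.0363), the adipocyte regulator Cebpb (0.108), the neural genes Syn1 (0.0837) and Olig2 (0.137), and the serum response genes Ccn2 (0.0219) and Klf6 (0.0270) led the rest. Their amplitudes ran from 0.525 points (Mbd3) to 8.97 points (Syn1). Without replicate 3 of 24 h the window of Mael passed over its list alone (adjusted p 0.0440), as it did at a period of 28 h (0.0423).

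As a group, imprinted windows had a mean 24 h amplitude of 2.93 points against 1.99 points in random lists matched on level (percentile 98.9, one-sided adjusted p 0.142 over 13 lists), so no list passed. Immune and neural markers came next (2.64 against 1.77 points, adjusted p 0.411), and the other 11 lists had an adjusted p of 0.977. The spread of imprinted windows between libraries was also large, with a mean SD of 8.28 points against 5.76 points in the same random lists (percentile 99.8). In the same one-sided test, the imprinted list passed without replicate 2 of 18 h (adjusted p 0.0169), replicate 3 of 30 h (0.0494) or replicate 2 of 48 h (0.0286), without all libraries numbered 2 (0.0130), at periods of 20 h (0.0130) and 28 h (0.0364), and with linear time as a further term (0.0468).

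Over the genome, no position, region or gene-end window passed for a 24 h rhythm. The positions with the smallest p-values lay within Exph5 (chromosome 9, 53301902; amplitude 8.75 points), Myod1 (chromosome 7, 46376753; 8.57 points), Hoxb7 (chromosome 11, 96287167; 10.7 points), Mboat2 (chromosome 12, 24831750; 7.22 points) and Slc25a5 (chromosome X, 36796101; 8.28 points), all with an adjusted p of 0.953. Regions with the smallest p-values included those near Ywhag (4.46 points), Vsig8 (5.22) and Lrig2 (3.24) and within Prps1l3 (1.72), and windows were led by those of Septin8 (2.66), N4bp1 (1.65), Zdhhc22 (5.12), Efs (3.56) and Zc3h10 (1.09). With limma, 0 of 871894 positions passed and 34063 (3.91%) had an unadjusted p under 0.05; 0 of 18447 regions (800 unadjusted) and 0 of 12512 windows (530 unadjusted) passed. Simulated rhythms with an amplitude of 5 points were recovered at 74.5% of windows, 68.5% of regions and 50.5% of positions (of 100000), and those of 2 points at 37.0%, 25% and 4.50%. The upper limit of the amplitude lay under 5 points at 80.4% of windows and under 10 points at 95.7%. Among windows with a mean level of 10% to 90% these shares were 43.9% and 86.5%, against 95.9% and 99.6% among windows under 10%, and 38.3% of regions of 10% to 90% had a limit under 5 points. On the M-value scale 1 window passed, that of N4bp1, an inhibitor of a ubiquitin ligase (mean level 1.62% ± 1.67; adjusted p 0.0429). Without replicate 3 of 36 h, 1 position passed, the one within Exph5 (adjusted p 0.0101).

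A steady drift from 12 h to 60 h was asked of genes of muscle differentiation and of the methylation machinery. Per 48 h, the fitted slopes were -1.72 points (SE 3.19) at Myod1, 0.964 (SE 2.02) at Myog, the myogenin gene, whose lower end stood at 83.9% ± 3.43, 1.66 (SE 2.40) at the skeletal actin gene Acta1 (12.4% ± 4.09) and 0.722 (SE 1.58) at the desmin gene Des (12.2% ± 2.66). The insulin-responsive glucose transporter gene Slc2a4 (19.5% ± 3.18) had 0.756 (SE 1.88), the de novo methyltransferase gene Dnmt3b (1.61% ± 1.32) -0.580 (SE 0.808), and Tet2, which encodes an enzyme that oxidises methylcytosine (5.15% ± 7.31), -1.76 (SE 4.29). None passed, and Myf5, Ckm, Pdk4, Ppargc1a, Dnmt1, Dnmt3a, Tet1 and Tet3 had no window. No window of any list passed over all windows or adjusted over the list alone; the smallest such adjusted p was 0.0732, in the germline list.

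The windows with the smallest trend p-values in the lists, none of which passed, included Nr1d2 (1.60 points per 48 h) and Npas2 (2.90) of the clock list, Id2 (1.64) and Six4 (2.27), Ryr1 (-8.65) and Mybpc2 (-5.59), Mcm2 (1.58) and Aurkb (1.51), and Uhrf2 (-2.88) and Dnmt3l (-8.11). Metabolic windows were Pygm (-6.19), the muscle glycogen phosphorylase gene, Foxo3 (-1.82), the carnitine palmitoyltransferase gene Cpt1a (11.6) and Esrra (-2.46). Others were Dlx5 (11.7) and Nnat (-1.95), Sycp2 (9.42) and Zfp42 (4.64), Hoxb6 (5.37) and Tbx2 (-2.57), Lep (9.56) and Pdgfra (17.3), Gfap (-7.60) and Neurog1 (-1.78), and Fos (-1.97) and Klf6 (-2.21). Over its list alone, Sycp2, a gene of the meiotic axis, passed without replicate 2 of 12 h (adjusted p 0.0430), replicate 3 of 24 h (0.0369), replicate 1 of 30 h (0.0467, with Zfp42), and replicate 1 (0.0242) or 3 (0.0304) of 48 h. Ryr1 passed without replicate 1 of 60 h (0.0250). Without all libraries numbered 1, Zfp42 (0.0249), Ddx4 (0.0225) and Hoxb6 (0.00119) passed, and with the library mean as a covariate Sycp2 (0.0386), Tex19.1 (0.0386) and Zfp42 (0.0439).

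With camera, no list had slopes apart from those of other windows. The smallest adjusted p was 0.391 for the myogenic regulators, upward (median slope 0.685 and mean 1.11 points per 48 h; p = 0.0301), which had an adjusted p of 0.701 with an estimated correlation. At 60 h against 12 h, the smallest adjusted p was 0.871 (0.895 with an estimated correlation), so there was no call to hold with either correlation. Signs differed between the median, the mean and the test in several lists: for the slope, core clock (median -0.0332, mean 0.00756, test up), glucose metabolism (0.251, -0.0822, down), imprinted (0.650, -0.871, down), Hox and developmental (-0.0558, 0.434, up) and immune and neural (0.855, -0.810, down). For 60 h minus 12 h they differed in muscle structure (-0.123, 0.735, up), DNA methylation enzymes (0.0315, -0.844, down), glucose metabolism (-0.134, 0.187, up), germline (-0.575, 0.365, up), fibroblast and adipocyte (-0.0133, 4.15, up), lipid and mitochondrial (0.265, 0.331, down) and immediate-early genes (-0.0739, 0.0372, up).

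Over the genome no drift passed either. The positions with the smallest p-values lay within Ppara (11.4 points per 48 h), a regulator of fatty acid oxidation, Vsig10l (-7.45), Rag1 (12.2), Gm37013 (-6.65) and Vmn1r4 (-15.9), all with an adjusted p of 0.975. Regions were led by those within Prkg1 (7.27), Mcrip2 (-4.06), Rag1 (8.61) and Chadl (-9.57) and near Fos (1.87), and windows by Rlim (16.9), an X-linked ubiquitin ligase gene that regulates Xist, Stpg2 (8.39), Mcrip2 (-3.76), Mphosph9 (2.22) and Tmem74 (-4.89). With limma, 0 of 871894 positions (39050 at an unadjusted p under 0.05), 0 of 18447 regions (920) and 0 of 12512 windows (601) passed. Simulated trends of 10 points were recovered at 75% of windows, 67.5% of regions and 54.0% of positions (of 100000), and those of 5 points at 46.0%, 36.0% and 11.5%. The limit given above for the shares of simulated rhythms holds here too.

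Differences between time points without an assumed shape were found at 36 positions in 9 site groups, most of them at places that were nearly unmethylated at the other times. Near the lower end of C87436, the group at chromosome 6, 86438443 to 86438448, had a level of 29.6% ± 6.42 at 12 h (SD, n = 3) against 2.26% ± 1.87 in the other 24 libraries (adjusted p 4.03e-05). At its position 86438445 the 12 h libraries stood at 33.3333%, 33.3333% and 22.2222%. These are simple fractions, such as a low number of reads can give, and the depth is unknown. Within Hic2, a gene of a transcriptional repressor, the group at chromosome 16, 17233969 to 17233994, stood at 11.4% ± 1.47 at 42 h against 0.305% ± 0.630 (adjusted p 9.8e-06). At 12 h, the chemokine gene Cxcl12 (chromosome 6, 117168697 to 117168700; 12.1% against 2.73%) and the non-coding RNA genes 4921531C22Rik (chromosome 2, 179977066 to 179977072; 9.24% against 0.988%) and 5033430I15Rik (chromosome 13, 45965805 to 45965813; 16.2% against 2.55%) were higher. Zfp871 (chromosome 17, 32788130 to 32788152; 9.93% against 0.548%) and Herpud2 (chromosome 9, 25151562 to 25151583; 8.88% against 0.519%) were higher at 54 h. Podxl2 (chromosome 6, 88842748 to 88842762; 13.9% against 1.05%) was higher at 60 h. Hs6st2, a heparan sulfate sulfotransferase gene (chromosome X, 51681268 to 51681269), was not set apart at a single time. Its mean was highest at 18 h (62.6%), but libraries of 24 h (60.4%, 54.0% and 61.1%) overlapped with those of 18 h (56.5%, 64.9% and 66.2%), and those of 12 h were at 38.9%, 46.5% and 38.6%.

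In 100 draws of the time labels, the real one included, 49 gave at least 36 positions, and the median of the other draws was 35, so the count did not exceed that of shuffled labels. The draws ignored replicate number, whereas each real time point has 1 library of each number. Differences between numbers can therefore add calls to the draws, and draws within numbers were not made. The test was the 8 degree of freedom F test of limma, with 36344 positions (4.17%) at an unadjusted p under 0.05 and adjusted p-values of the named groups from 9.8e-06 to 0.0379. Only the groups at C87436 and Hic2 passed in all 4 of the fits with another scale, block, covariate or moderation. Hs6st2 was lost without replicate 2 of 18 h (adjusted p 0.0634), replicate 3 of 24 h (0.0571) or replicate 1 of 60 h (0.0531), Cxcl12 without replicate 2 (0.0841) or 3 (0.131) of 12 h, and 4921531C22Rik without replicate 1 (0.0816) or 3 (0.121) of 12 h. The count was 12 positions on the M-value scale, 20 with a replicate block, 86 where 2 of 3 values per time point sufficed and, in a fit chosen after seeing the data, 1 at 1 position per 80 bp, at C87436 (chromosome 6, 86438443). Among 217225 positions of 10% to 90% it was 0 (9815 unadjusted), but 8 of the 9 groups have a lower mean level and were not in that fit; the remaining one, Hs6st2, did not pass (adjusted p 0.890). Each fit that left out 1 library gave more than 36 positions. Without replicates 1, 2 and 3 in turn, the count was 188, 145 and 109 for 12 h, 267, 111 and 136 for 18 h, and 97, 85 and 54 for 24 h. It was 72, 104 and 108 for 30 h, 82, 171 and 86 for 36 h, and 71, 109 and 119 for 42 h. It was 116, 513 and 78 for 48 h, 145, 92 and 124 for 54 h, and 40, 94 and 51 for 60 h. Without all libraries numbered 1, 2 or 3 it was 117, 232 and 131. Of the 9 groups, only Hic2, only Podxl2, and only C87436 and Hic2 still passed in these fits, in that order. Simulated shifts of 1 time point by 20 points were recovered at 39.0% of positions and those of 10 points at 19% (of 100000), with 33 and 24 unchanged positions called. These shifts went up or down and were cut at the ends of the scale. The shares therefore do not give the power for upward shifts alone. Shifts of 2 points were recovered at 0% of positions, with 9 unchanged positions called. In these simulated data the share of false calls exceeded the threshold of 0.05. Adjusted p-values of this test may therefore be too small.

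**Figure D5:**
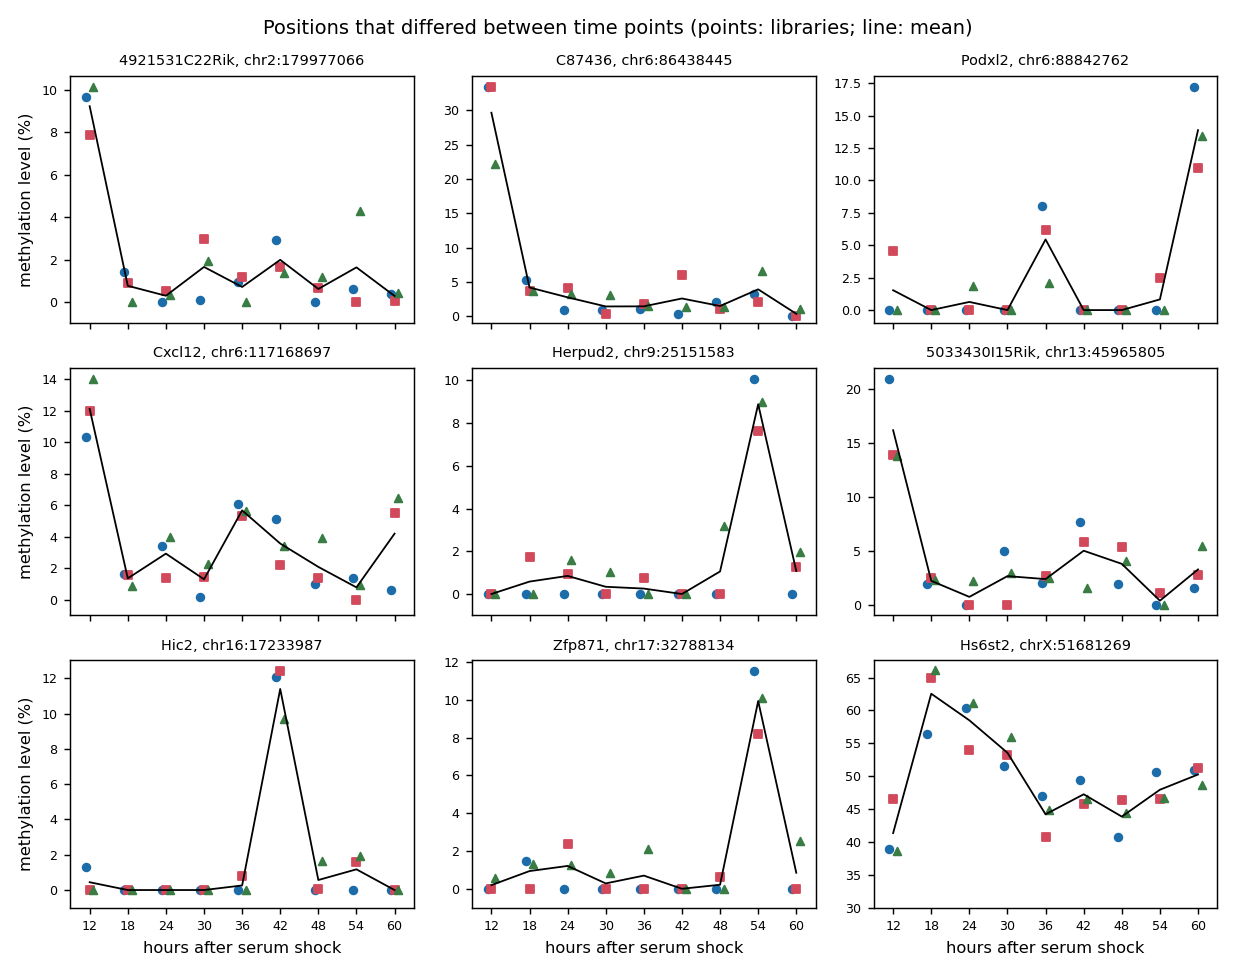
Methylation level (percent, y axes, scaled per panel) at the position with the smallest p-value in each of the 9 site groups, against hours after the serum shock (x axes); symbols are single libraries by replicate number and lines the time point means. C87436 stands at 29.6% at 12 h and Hic2 at 11.4% at 42 h; the Hs6st2 panel starts at 30%.

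At the end of the course against its start, 61 positions in 12 site groups differed, 8 groups lower and 4 higher at 60 h. Lower at 60 h were positions at C87436 (29.6% ± 6.42 at 12 h and 0.345% ± 0.597 at 60 h; SD, n = 3). Others lay 1471 bp outside the adhesion receptor gene Adgrl2 (chromosome 3, 148990567 to 148990607; 23.9% ± 5.18 and 5.52% ± 1.83) and at the translation termination factor gene Gspt1 (chromosome 16, 11254171 to 11254189; 11.5% ± 4.08 and 0.0525% ± 0.0140). Also lower were 5033430I15Rik (16.2% and 3.27%), 4921531C22Rik (9.24% and 0.280%), the positions shared by Mrpl48 and Rab6a (chromosome 7, 100608136 to 100608147; 10.5% and 0.379%) and Eml6 (chromosome 11, 30025880; 10.1% and 2.03%). Higher at 60 h were the matrix protein gene Npnt (chromosome 3, 132950142 to 132950143; 2.38% ± 2.14 and 14.9% ± 3.23), Podxl2 (chromosome 6, 88842739 to 88842762; 1.40% ± 2.43 and 12.6% ± 3.27), the centriolar satellite gene Pcm1 (chromosome 8, 41240192 to 41240216; listed at 0 in all 12 h libraries and 7.90% ± 1.33) and a position 345 bp outside the nuclear pore gene Ranbp2 (chromosome 10, 58446507; 0.710% ± 1.23 and 23.8% ± 9.91).

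Adjusted p-values of limma ran from 1.45e-05 (C87436) to 0.0478 (Eml6), and 4 groups with 18 positions were shared with the test between time points. Only the group at C87436 passed in all 4 of the fits with another scale, block, covariate or moderation, and it also passed without the libraries of any 1 replicate number. Its 12 h levels are the simple fractions given above, at unknown depth. Of the 12 groups, 3 passed without the libraries numbered 1, 4 without those numbered 2 and 1 without those numbered 3. Npnt was lost without replicate 3 of 12 h (adjusted p 0.0531), replicate 2 of 36 h (0.0517) or replicate 1 (0.0950) or 2 (0.0587) of 60 h. Mrpl48 was lost without replicate 2 of 36 h (0.0517) or replicate 1 (0.0695) or 3 (0.0576) of 60 h. Adgrl2 (0.0592) and 5033430I15Rik (0.0525) were lost without replicate 1 of 60 h. Ranbp2 passed only without replicate 1 or 2 of 12 h, 1 or 2 of 24 h, 2 of 30 h, 1 or 3 of 42 h or 2 of 60 h, and had an adjusted p of 0.0511 to 0.118 in the 19 other fits that left out 1 library. Eml6 passed only without replicate 1 of 12 h, 1 of 36 h, 2 or 3 of 42 h or 3 of 54 h, with 0.0507 to 0.112 in the 22 others. The count was 3 on the M-value scale, all at C87436. Among positions of 10% to 90% it was 0 (12433 unadjusted), but of the 12 groups only that near Adgrl2 was in that fit (adjusted p 0.268). At 1 position per 80 bp it was 4, among them positions at C87436 and Gspt1 and near Adgrl2. It was 515, 397 and 360 without replicates 1, 2 and 3 of 12 h, 124, 218 and 142 without replicates 1, 2 and 3 of 60 h, and 92 and 114 without all libraries numbered 1 and 2. Simulated differences of 20 points were recovered at 41% of positions, those of 10 points at 21% and those of 5 points at 3.0% (of 100000), with 13, 8 and 5 unchanged positions called. They too went up or down and were cut at the ends of the scale, so the shares do not give the power for upward differences alone. At each of these sizes the share of false calls exceeded the threshold of 0.05, so adjusted p-values may be too small here as well.

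Whether libraries 24 h apart resembled each other more than those 12 h or 36 h apart was asked with the correlation over all kept positions. The mean Pearson correlation was 0.922 for libraries 24 h apart (45 pairs), 0.921 for those 12 h apart (63 pairs) and 0.919 for those 36 h apart (27 pairs). The difference of 0.00161 was not detected (permutation p = 0.390), nor was that of 0.00774 over the 20000 most variable positions (permutation p = 0.421). It moved to 0.00271 and 0.00296 without replicates 2 and 3 of 24 h, 0.00268, 0.00105 and 0.00103 without replicates 1, 2 and 3 of 36 h, 0.000841 and 0.000622 without replicates 1 and 3 of 48 h, and 0.000761 without all libraries numbered 3. Over the 20000 most variable positions it moved to 0.0126 and 0.0141 without replicates 2 and 3 of 24 h, 0.0133 without replicate 1 of 36 h, 0.00334 and 0.00431 without replicates 1 and 3 of 48 h, and 0.00485 without replicate 2 of 60 h. Both differences stayed positive in each of these fits.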

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

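The fit on 1 position per 80 bp was chosen after the data were seen, and the other alternatives were planned. Without counting fits that left out libraries, 78 of the counts and library values kept their direction and their side of the threshold (or stayed within 1.5 times), 9 were weaker, 6 stronger and 1 reversed. For positions differing between time points (36), the M-value scale gave 12, the replicate block 20, positions of 10% to 90% 0 (217225 tested, 9815 at an unadjusted p under 0.05 with limma), 1 position per 80 bp 1 (96222 tested) and 2 of 3 values per time point 86 (922260 tested); for 60 h against 12 h (61), the M-value scale gave 3, positions of 10% to 90% 0 (12433 unadjusted) and 1 position per 80 bp 4. The counts of 0 follow largely from the filter, which kept 1 of the 9 and 1 of the 12 site groups (Hs6st2, adjusted p 0.890, and Adgrl2, 0.268). The fit on 1 position per 80 bp chose positions by coordinate alone, so it can leave out called positions as well as their neighbours. The cause of the other shifts was not tested. Gene-end windows with a rhythm numbered 1 on the M-value scale (0 otherwise); windows with a rhythm over the list alone (1) numbered 0 on the M-value scale and 0 at a period of 20 h; windows with a trend over the list alone (0) numbered 3 with the library mean as a covariate; and lists with a larger amplitude than random lists (0) numbered 1 at 20 h, 1 at 28 h and 1 with linear time as a further term. The global slope of -0.00857 reversed to 0.116 points per 48 h (SE 0.369) over positions of 10% to 90%. Leaving out 1 library or 1 replicate number gave 40 to 513 positions between time points, 41 to 515 for 60 h against 12 h, 0 to 1 position with a rhythm, 0 to 1 window with a rhythm and 0 to 3 with a trend over the list alone, and 0 to 1 list with a larger amplitude. It gave 0 to 0 for positions with a trend, for regions with a rhythm or a trend, for windows with a rhythm and for lists tested with camera on the slope or on 60 h against 12 h. The range of time point means was then 0.172 to 0.817 points, the global amplitude 0.0843 to 0.239, the global slope -0.187 to 0.251 (reversed in 10 fits), the similarity difference 0.000622 to 0.00296 and that over the 20000 most variable positions 0.00334 to 0.0141. The main fits did not use the replicate numbers to pair the samples. Deviations from the time point means correlated only between -0.0227 and 0.0239 over 108 same-numbered pairs, which does not exclude a shared effect of the number. The data, though not the design, point to such an effect. Of the 27 libraries, 20 correlated best with a library of their own number. Number 1 had the lowest level over positions above 90% at 9 of 9 time points (permutation p = 4e-05, numbers permuted within time points). The permutation tests of library means and of the similarity of libraries used no block. Apart from the 20 positions above, the replicate block gave 55 positions for 60 h against 12 h and changed no other count by over 1.5 times. Among the named windows and site groups, 150 values kept their side of the threshold and 34 were weaker without leaving out a library. In the fits that left out libraries, 1028 of their values kept their side and 112 were weaker. Of the counts and library values in those fits, 450 stayed the same by the rule above, 47 were stronger, 3 weaker and 10 reversed. Depth is unknown, so no limit set by reads can be given; libraries differed in the share of positions at exactly 0 (5.15% to 25.4%) and in their residual SD (4.36 to 7.62 points).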

Other observations

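The tests of 12 h against all other times, of conversion as the only cause of the spread of library means, of replicate number and of depth, and the tests of regions and gene-end windows between time points were chosen after the results they bear on had been seen.

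Neighbouring Hox genes, which set position along the body axis, differed widely in level, and the windows named here were chosen after their values were seen. In the Hoxa cluster on chromosome 6, the higher end of Hoxa2 stood at 98.4% ± 1.39 (SD over 27 libraries) and that of Hoxa5 at 95.2% ± 1.49, against 2.93% ± 1.68 at the higher end of Hoxa10 and 6.66% ± 1.37 at that of Hoxa11. Hoxa13 stood at 93.9% ± 3.70 at its lower end and at 2.81% ± 3.35 at its higher end. In the Hoxc cluster on chromosome 15, the lower end of Hoxc8 stood at 81.9% ± 4.57 between those of Hoxc9 (4.48% ± 2.69) and Hoxc6 (1.78% ± 2.29). Some genes of muscle metabolism also had a highly methylated end in a list with a low median: the mitochondrial uncoupling protein gene Ucp3 at 95.2% ± 5.13, the carnitine palmitoyltransferase genes Cpt1b at 84.8% ± 1.80 and Cpt1a at 80.7% ± 7.70, and the lactate dehydrogenase gene Ldha at 85.7% ± 6.71.

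Between time points, 3 of 12512 gene-end windows passed (limma, 487 at an unadjusted p under 0.05). The lower end of Pnpla2, the gene of the lipase that begins the breakdown of stored fat (chromosome 7, 141454188 to 141455688), had a level of 18.8% ± 5.82 at 48 h (SD, n = 3) and of 0.467% to 3.50% at the other times (adjusted p 0.0076). Prps1l3 (chromosome 12, 57229412 to 57230912) had 6.06% ± 1.48 at 18 h against a mean of 1.70% over 27 libraries, and the window of its neighbour Mipol1 (57229425 to 57230925), which covers nearly the same positions, 6.02% ± 1.37 (adjusted p 0.0351 for both). Of 18447 regions, 1 passed (793 unadjusted), that within the Pnpla2 window (141455481 to 141455673; adjusted p 0.0138). The Pnpla2 window was lost without replicate 1 of 48 h (adjusted p 0.075) and on the M-value scale (0.839). Those of Prps1l3 and Mipol1 were lost on the M-value scale (0.126 for both). Both passed with a replicate block (0.0487), the library mean as a covariate (0.0235) and trended and robust moderation (0.00713). Of the fits that left out 1 library, they passed only in those without replicate 2 of 18 h, 1 or 3 of 42 h, 2 or 3 of 48 h, 1 or 2 of 54 h, or 2 or 3 of 60 h. Over the other fits that left out 1 library their adjusted p lay between 0.0523 and 0.334. Pnpla2 alone passed without any 1 library of 12 h, 30 h or 36 h, replicate 1 or 3 of 18 h, 1 of 24 h, 2 of 42 h, 3 of 54 h or 1 of 60 h. The count was 12 without replicate 2 of 48 h, 5 without replicate 1 of 54 h (the 3 with Jpt2 and Cramp1l), 5 without replicate 3 of 60 h (with Snrpg and Rtp2), and no window passed without replicate 1 of 48 h. The region was lost without replicate 1 (adjusted p 0.226) or 2 (0.0561) of 48 h, on the M-value scale (0.903) and with the library mean as a covariate (0.0509). Another region passed without replicate 2 (near Ston1) or 3 (Mael) of 24 h, 3 of 30 h (Atp5d), 3 of 36 h (H3f3a), 3 of 42 h (Gprc5a), 3 of 48 h (Cycs) or 1 of 54 h (Jpt2), and 2 further regions (near Mrpl36 and Prkcd) without replicate 1 of 18 h. Without all libraries numbered 1, 2 or 3, none of the 3 windows and not the region passed. At 60 h against 12 h, in limma tests also chosen after the data were seen, 0 of 12512 windows passed (641 unadjusted, smallest adjusted p 0.103). Of 18447 regions, 0 passed in that comparison (984 unadjusted, smallest adjusted p 0.336).

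Of 100 draws of the time labels, the real one included, 5 gave at least 3 windows (highest other 3) and 28 at least 1 region (highest other 3), so chance was not excluded for either count. It was not excluded for the counts of positions either. All these draws ignored replicate number, so differences between numbers can add calls to them. Of the same draws, 49 gave at least the 36 positions found between time points; the median of the other draws was 35, close to the real count. The highest other draw gave 211, several times the real count, which may come from a structure of the libraries or from calls that cluster at neighbouring positions; neither was tested. As many or more features at an unadjusted p under 0.05 came in 50 draws for the rhythm of positions (34063, highest other 39644), 70 for that of regions (800, 986), 72 for that of windows (530, 713), 50 for the trend of positions (39050, 50910), 35 for that of regions (920, 1295) and 49 for that of windows (601, 940). For 60 h against 12 h, the 10 splits of the 6 libraries are too few for a share under 0.05; 1 split, the real one, gave 61 positions, and the highest other gave 23.

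At 4 of the 9 site groups that differed between time points, 12 h was the time farthest from the rest. Against all other times, 12 h had 1036 positions in 221 site groups, while 48 h had 2004, 18 h 1351, 42 h 693, 30 h 576, 54 h 430, 36 h 395, 24 h 290 and 60 h 143. Of 100 triples with 1 library from each of 3 time points, 37 gave at least 1036 positions (highest 3830), so a chance triple was not excluded. Of 100 triples of other libraries with a residual SD within 0.5 points of that of 12 h, 78 did (highest 7755). Neither set of triples was matched on replicate number, whereas 12 h has 1 library of each number. Noisier libraries may be enough to give as many calls, but differences between replicate numbers can add to the calls of the triples. An effect of the time since the serum shock stays open for these positions, and no test here separates it from noise.

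Library means spread from 11.4% to 12.7% within and between time points. Incomplete bisulfite conversion, which leaves unmethylated cytosines read as methylated, is a candidate explanation for part of it: the mean followed the level at positions under 5% (Pearson r = 0.920, Spearman rho = 0.851, both permutation p = 1e-05, the smallest possible, adjusted 3e-05 over 6 relations; r = 0.849 without the 2 farthest libraries and 0.938, 0.966 and 0.954 within replicate numbers 1, 2 and 3). Those positions are part of the mean, but over disjoint positions, those of 10% to 90% against those under 5%, r was still 0.661 (rho = 0.681; permutation p = 0.0001 and 0.00014; 0.517 without the 2 farthest; 0.437, 0.660 and 0.795 within numbers). As the only cause it was argued against by the slope of that second relation, 1.81 ± 0.412 (SE) against at most 0.667. Replicate number, whose meaning the labels do not give, is another candidate explanation for part of the spread. At positions of 10% to 90%, numbers 1, 2 and 3 had means of 34.1%, 35.0% and 34.9% (permutation p = 0.00761, numbers permuted within time points), and number 1 was the lowest at 7 of 9 time points. Over positions above 90% the means were 94.2%, 94.6% and 94.6% (permutation p = 4e-05), with number 1 lowest at 9 of 9. For the mean over all positions it stayed open (11.7%, 12.0% and 12.0%; permutation p = 0.0581; number 1 lowest at 6 of 9). The library mean also followed the level at positions above 90% (r = 0.553, rho = 0.571, adjusted permutation p 0.00604 and 0.00456), with r of 0.0967, 0.582 and 0.207 within numbers. Depth stayed open, read through the share of positions at exactly 0 (r = -0.383, rho = -0.469, permutation p = 0.0487 and 0.0146, adjusted 0.0725 and 0.0219; r = -0.229 without the 2 farthest, and 0.0978, -0.385 and -0.172 within numbers). Positions at 0 are part of the mean and lower it, so that relation is not a clean reading of depth. A relation to the number of positions missing was not detected (r = -0.369, adjusted permutation p 0.0725). Neither was a relation to the residual SD (r = -0.131, adjusted permutation p 0.516). No biological explanation was tested.

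The intermediate level of X-linked gene ends may reflect X inactivation, in which 1 of 2 X chromosomes is silenced and its gene starts are methylated. The 4 windows of genes known to escape inactivation, from a list of 8 written before the test, were low: Kdm5c at 2.25% ± 1.5, Ddx3x at 2.65% ± 2.34, Pbdc1 at 3.45% ± 1.38 and Eif2s3x at 4.37% ± 2.01 (SD over 27 libraries). Their median of 3.05% lay below that of the other X windows, 33.6% (one-sided permutation p = 2e-05). The number of X chromosomes in these cells was not measured here, and no other explanation was tested.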
